A study of Homo sapiens with 3 samples.

How the data were processed

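Gene expression was measured in KYSE150 cells, an established human oesophageal squamous carcinoma line, 48 h after transfection with an empty vector, with a plasmid for the wild-type form of LOXL2 (LOXL2 WT) or with a plasmid for the form named delta72 (LOXL2 delta72). Each of the 3 conditions was represented by 1 array. Per the labels' protocols, biotin-labelled cRNA was made from 100 ng of total RNA and hybridised to an Affymetrix 3' expression array. The submitters' processing notes name Partek and Affymetrix Expression Console, without versions, and the normalization algorithm and any background correction are not given in the sources used here.

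The authors deposited 1 table with a value for each of 49395 probe sets on each array. The deposited values were taken as log2 intensities, because all of them lay between 2.07 and 14.56, the span of log2 brightness of a scanner. The median over all probe sets was 5.95 on the control array, 5.93 on the WT array and 5.94 on the delta72 array, so the arrays had been brought to a near-common scale before deposit. Log2 differences are relative to that scale, and a shift shared by most genes would not be visible in them. How far the authors' background correction compressed the differences of dim probe sets is not known.

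Of the probe sets, 102 were Affymetrix controls and 49293 were others. Among the others, 44988 were paired with 1 gene symbol, 1832 with several and 2473 were not listed in the annotation table used here. Genes were named only from probe sets with 1 symbol. Entrez identifiers of 44967 of these 44988 probe sets were found in the RefSeq gene table, and 0 symbols had to be updated. The probe sets stood for 18132 genes. Each gene was represented by the probe set with the highest mean over the 3 arrays, and genes were kept when that mean reached the 40th percentile of all non-control probe sets (log2 5.27), which left 12232 genes. Of these, 7163 had more than 1 probe set above the filter, and the standard deviation of the difference between those probe sets is given as probe error. It describes probes on the same arrays and includes no biological or hybridisation error.

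With 1 array per condition there is no replicate spread, so no significance test was made and no p-value is given. The precision is limited by the number of arrays. The 3 log2 differences computed for each gene were LOXL2 WT minus control, LOXL2 delta72 minus control, and LOXL2 delta72 minus LOXL2 WT. Genes at least 2-fold different were counted by size alone. The genes named in the text were chosen by a rule. It took the lysyl oxidase family, in each comparison the 10 genes with the highest and the 10 with the lowest difference, where the median over a gene's probe sets had the same sign, the 5 genes with the largest difference shared by both forms in each direction, and up to 4 members of each gene list with the largest difference. Genes outside this rule are said to be so.

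Groups of genes were described with 26 gene lists and 4 lists of markers of other cell types, all fixed in advance. The median difference of a list's members above the filter was placed among the medians of 10000 random lists of the same size drawn from the same deciles of mean expression. A list was described as standing apart when its median lay outside the central 95% of the random lists. This describes these arrays and does not test the conditions. The number of members at least 1.5-fold different was counted as well. The standard error of a list median was taken from the pooled probe error (log2 0.170 for WT minus control, 0.145 for delta72 minus control and 0.113 for delta72 minus WT).

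The differences of both forms from the control use the same control array, which makes them correlate without any effect. Their correlation and covariance across genes are therefore given beside those of 100 simulations of 3 unchanged arrays, whose spread was taken from the delta72 minus WT differences. The control array could not be split.

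The counting was tested on simulated data for LOXL2 WT against control, over 12215 genes. All 94 genes given a 3-fold difference were counted at 2-fold, against 1 of 99 genes given a 1.5-fold difference and 0 of 12022 unchanged genes. The simulated noise was taken from the delta72 minus WT differences, the closest pair of arrays. Over genes their SD was 0.132, against 0.255 for WT minus control. The simulation therefore checks the counting and does not give the share of false counts between the real WT and control arrays. Of 100 lists of unchanged genes, 4 lay outside the central 95% of random lists. The simulated noise was independent between genes, so this share followed from the construction. It does not calibrate lists of genes that move together.

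The alternatives planned were a shift of each array to a common median over the genes that passed the filter, quantile normalization, the median over a gene's probe sets in place of the brightest one, no filter, a filter at the 60th percentile (log2 6.65), and thresholds of 1.5-fold and 3-fold. Other pseudocounts were planned only for linear values and were not needed. A lowess correction of each LOXL2 array's difference from the control on mean brightness (fraction 0.3) was added after the control probe sets had been seen. The work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.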

Results

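The data set holds 3 Affymetrix expression arrays of KYSE150 cells, a line derived from a human oesophageal squamous carcinoma. The cells had been transfected with an empty vector, with LOXL2 WT or with LOXL2 delta72, a form that the labels name without describing it, and RNA was taken 48 h later. The 3 arrays allow the comparison of each form with the vector and of the forms with each other. LOXL2 is lysyl oxidase like 2, a copper-dependent amine oxidase that crosslinks collagen and elastin. Each condition had 1 array, so the differences described here have no replicate check, and "higher" and "lower" refer to these arrays. The deposited log2 values of the arrays correlated across probe sets with Pearson's r of 0.995 for WT and control, 0.996 for delta72 and control, and 0.998 for delta72 and WT.

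The transfected gene was read first. LOXL2 was far higher on both LOXL2 arrays than on the control array. Its brightest probe set read log2 7.46 on the control array, 14.05 on the WT array and 14.06 on the delta72 array, which is 96.1-fold and 96.8-fold above control. A probe set that read 5.06 on the control array, below the filter value, read 10.22 on both LOXL2 arrays, and one that read 5.38 read 8.07 and 8.02. Background probe sets read from 2.47 at 10 G and C bases to 10.84 at 25 on the control array, so it is not known whether the control values of LOXL2 lie above background. The fourth probe set, at 8.81 on the control array, was lower with WT, at -0.48, and with delta72, at -0.14. The SD of the WT minus control difference over these 4 probe sets was 3.10. The brightest probe set lay 0.51 below the highest value on the WT array, so its fold may be compressed. It read 1.01-fold higher with delta72 than with WT. Probe positions are not given in the sources used here, so the probe sets do not tell the forms apart.

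**Figure D1:**
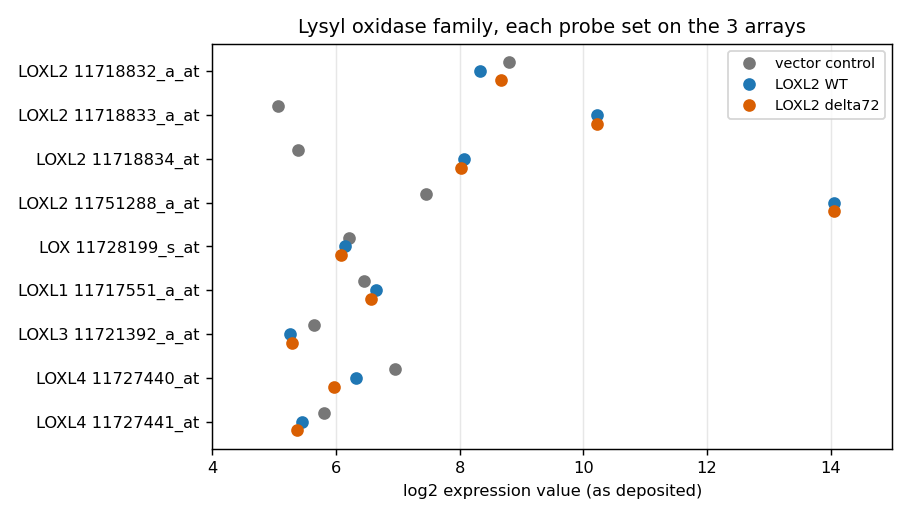
Log2 expression values as deposited (x axis) of the LOXL2 probe sets and of the other lysyl oxidase family probe sets above the filter (y axis), with 1 point per array. The brightest LOXL2 probe set lies at 7.46 for the vector control and at 14.05 and 14.06 for the LOXL2 arrays, while 1 of the 4 LOXL2 probe sets is highest on the control array, at 8.81.

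The other lysyl oxidases stayed within 2-fold of control. LOXL4 was lower on both arrays, at -0.63 with WT (SD 0.19 over 2 probe sets) and at -0.99 with delta72 (SD 0.39), or 1.54-fold and 1.98-fold. LOXL3 differed by -0.40 and -0.36, LOXL1 by 0.20 and 0.10, and LOX by -0.06 and -0.14, each on 1 probe set above the filter. LOXL3 lay near the filter value of 5.27, at 5.25 on the WT array, and its dimmer probe set differed by 0.17 and 0.22. Further LOX probe sets below the filter differed in either direction.

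On these 2 arrays, cells given LOXL2 WT differed from the vector control in stress, lipid synthesis and cell division genes. The list medians for stress and cell division were smaller in size than the largest difference of a background probe set, 0.285. Apart from LOXL2, the highest genes were ARRDC4, an arrestin-domain gene related to TXNIP, at 1.51 (2.85-fold, SD 0.11 over 2 probe sets), the transporter gene ABCA13 at 1.46, and GEM, which encodes a small GTP-binding protein, at 1.38. The lowest genes were EHF, an epithelial ETS transcription factor, at -1.66 (3.16-fold lower, 1 probe set), and PHLDA1 at -1.24 (2.36-fold lower, SD 0.29 over 4 probe sets). All 13 cholesterol synthesis genes above the filter were lower, and so were 22 of 24 mitotic genes and 15 of 19 hypoxia and glycolysis genes.

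In this comparison 22 genes, LOXL2 among them, were at least 2-fold higher and 12 at least 2-fold lower with LOXL2 WT, out of 12232. When each array was shifted to a common median, the counts were 17 and 17. Of the 14 such genes with more than 1 probe set, 10 had all probe sets in the same direction. The remaining genes among the 10 highest were GRIP1 at 1.35, the nuclear receptor gene NR4A3 at 1.27, DHRS2 at 1.24, the zinc finger gene ZSCAN12 at 1.21, LIG4, the DNA ligase of non-homologous end joining, at 1.20, and ZNF425 at 1.17. The remaining genes among the 10 lowest were OSMR, which encodes a subunit of the oncostatin M receptor, at -1.18, GNE, the key enzyme of sialic acid synthesis, at -1.16, EXD3 at -1.10, CARD17P at -1.09, ZNF436-AS1 at -1.09, HILPDA, a hypoxia-induced lipid droplet gene, at -1.08 (SD 0.02 over 2 probe sets), the glycolytic gene ALDOC at -1.08 (SD 0.12 over 5 probe sets) and RDM1 at -1.05. The probe sets of OSMR disagreed (SD 0.73 over 3), and the median over them was -0.02.

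With LOXL2 WT, 3 of the 26 gene lists lay above the central 95% of random lists and 7 below it. Lists of randomly drawn genes would put 1.3 outside. Genes of a real list can move together between 2 single cultures, so the 1.3 is no measure of chance for these lists. In size, only the cholesterol synthesis and histone medians exceeded the largest background probe set difference between the WT and control arrays, 0.285. The cholesterol synthesis list had a median of -0.30, with 13 of 13 members lower, among them SQLE at -0.73, MSMO1 at -0.64 and FDPS at -0.51, which encode enzymes of the pathway. The EGFR family list had a median of -0.25 over 9 members, with EGFR itself at -0.67 and the ligand gene NRG1 at -0.51. The mitosis list had a median of -0.22, with CCNB2 at -0.44 and the kinesin gene KIF20A at -0.41, and none of its 24 members reached 1.5-fold. The hypoxia and glycolysis list had a median of -0.20, led by ALDOC, by ANKRD37, a target of hypoxia-inducible factor, at -0.86, and by ADM at -0.78.

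The NF-kB and cytokine list had a median of -0.18, with 10 of 15 members lower, among them IL1B at -0.92, IL1A at -0.76 and TNFAIP2 at -0.61. The list of NRF2 targets and AKR genes had a median of -0.14, with 12 of 17 members lower, including the pentose phosphate gene TKT at -0.50, while AKR1B10 was at 0.59. With the median over a gene's probe sets, the NRF2 list lay at the 5.55th percentile and no longer stood apart. The integrin and cytoskeleton list had a median of -0.13, with 16 of 24 members lower and the integrin gene ITGB5 at -0.58.

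The lists above random were the replication-dependent histones, the core spliceosome and SR proteins, and the unfolded protein and integrated stress response. The histone list had a median of 0.36 over 9 members, led by H2BC5 at 0.81 and H2AC6 at 0.61. The spliceosome list had a median of 0.15, with 13 of 19 members higher, among them the splicing factor genes SRSF2 at 0.43, TRA2B at 0.40 and SRSF3 at 0.36, and it no longer stood apart with the median over probe sets. The stress response list had a median of 0.13 and held members on both sides, with 14 of 22 members higher and 8 lower. With the 60th percentile filter its median was 0.23 over 19 members. DDIT3, the stress-induced transcription factor CHOP, was at 1.03, HSPA5, the main chaperone of the endoplasmic reticulum, at 0.93 and HERPUD1, which acts in degradation from the endoplasmic reticulum, at 0.88, whereas DDIT4 was at -0.66.

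Cells given LOXL2 delta72 differed from control in protein-folding stress genes, among others. Next to LOXL2, the highest genes were HSPA6, an inducible heat shock protein, at 1.84 (3.59-fold, 1 probe set), DDIT3 at 1.65 (3.14-fold, SD 0.05 over 2 probe sets), ARRDC4 at 1.55 (2.93-fold, SD 0.05 over 2 probe sets) and HERPUD1 at 1.45 (2.74-fold, SD 0.11 over 3 probe sets). The lowest genes were GNE at -1.35 (2.55-fold lower, 1 probe set), PHLDA1 at -1.21 (2.31-fold lower, SD 0.26 over 4 probe sets) and LOXL4. Lower genes also included the squamous genes KRT15, a basal keratin, at -0.90 and DSC3, a desmosomal cadherin, at -0.86.

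With delta72, 15 genes, LOXL2 among them, were at least 2-fold higher and 2 at least 2-fold lower. Of these, 7 of the 8 with more than 1 probe set had all probe sets in the same direction. The remaining genes among the 10 highest were ABCA13 at 1.41, SYTL2 at 1.31 (SD 0.15 over 2 probe sets), GEM at 1.30, ODC1, the first enzyme of polyamine synthesis, at 1.27, and DHRS2 at 1.23. The remaining genes among the 10 lowest were RAB26 at -0.94, the water and glycerol channel gene AQP3 at -0.94, EXD3 at -0.92, OLR1 at -0.91 and CASP1, an inflammatory caspase, at -0.87.

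Against the same control array, 3 lists lay above random lists with delta72 and 7 below. Lists that stood apart with both forms share that 1 array and are not an independent repeat. In size, the NRF2, integrin and DNA replication medians were below the largest background probe set difference between the delta72 and control arrays, 0.173. The unfolded protein and integrated stress response list had a median of 0.22, with 15 of 22 members higher and 7 at least 1.5-fold higher, including HSPA5 at 1.19 (SD 0.41 over 6 probe sets) and PDIA4 at 0.83 (SD 0.06 over 3 probe sets). With the 60th percentile filter its median was 0.35 over 19 members. The heat shock list had a median of 0.21, with 8 of 13 members higher and 2 at least 1.5-fold higher, which were HSPA6 and HSPA1B at 0.68. Among brighter genes only (60th percentile filter) the heat shock list lay at the 61.5th percentile. The histone list had a median of 0.38, with 8 of 9 members higher, including H2BC21 at 0.74, H1-2 at 0.72, H2AC6 at 0.70 and H2BC5 at 0.68. Its median depended on the filter and was 0.68 over 7 members at the 60th percentile.

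The cholesterol synthesis list was lower in 13 of 13 members, with a median of -0.24, SQLE at -0.71, MSMO1 at -0.65 and FDPS at -0.60. Its median between both forms, which does not use the control array, was 0.00923. A reading particular to the shared control array would give the same result. The EGFR family list had a median of -0.28, with NRG1 at -0.51. The basal squamous identity list had a median of -0.20, with 9 of 10 members lower, among them KRT15, KRT14 at -0.66 and the hemidesmosome integrin gene ITGB4 at -0.36. The mitosis list had a median of -0.19, with 23 of 24 members lower and KIF20A at -0.48. The NRF2 list had a median of -0.16, although AKR1B10 was at 0.72. The integrin list had a median of -0.12, with 18 of 24 members lower, and the DNA replication list had a median of -0.11, with 19 of 24 members lower. Without the filter on dim genes, the EGFR list lay at the 8.7th percentile and the NRF2 list at the 10.0th, and neither stood apart, whereas the hypoxia list, at 0.12, lay at the 98.9th percentile. With the median over a gene's probe sets, the NRF2 list lay at the 42.9th percentile.

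The effects of both forms were set against each other across genes. Among the genes with the largest difference in the same direction on both arrays were ARRDC4, ABCA13, GEM and DHRS2, besides LOXL2, on the higher side, and PHLDA1, GNE, RAB26, EXD3 and KRT15 on the lower side. RAB26 was at -1.04 and -0.94, and KRT15 at -1.0 and -0.90. In all, 118 genes were at least 1.5-fold higher on both arrays and 39 at least 1.5-fold lower on both. At 2-fold, 11 genes were higher and 2 lower on both. The counts of higher genes include LOXL2 itself.

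Across the 12232 genes, the WT and delta72 differences correlated with Pearson's r of 0.855 and Spearman's rho of 0.819. Genes are not independent replicates. Without LOXL2, r was 0.846. Unchanged arrays that share 1 control gave an r of 0.50 and a rho of 0.482 in simulation. The covariance was 0.0492 against 0.00876 simulated, a difference of 0.0405. The control could not be split, so all of the excess may come from this 1 control array. Of the 331 genes at least 1.5-fold different between WT and control, apart from LOXL2, 278 (84.0%) had a delta72 value between the control and WT values, which choosing genes on the WT array favours.

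**Figure D2:**
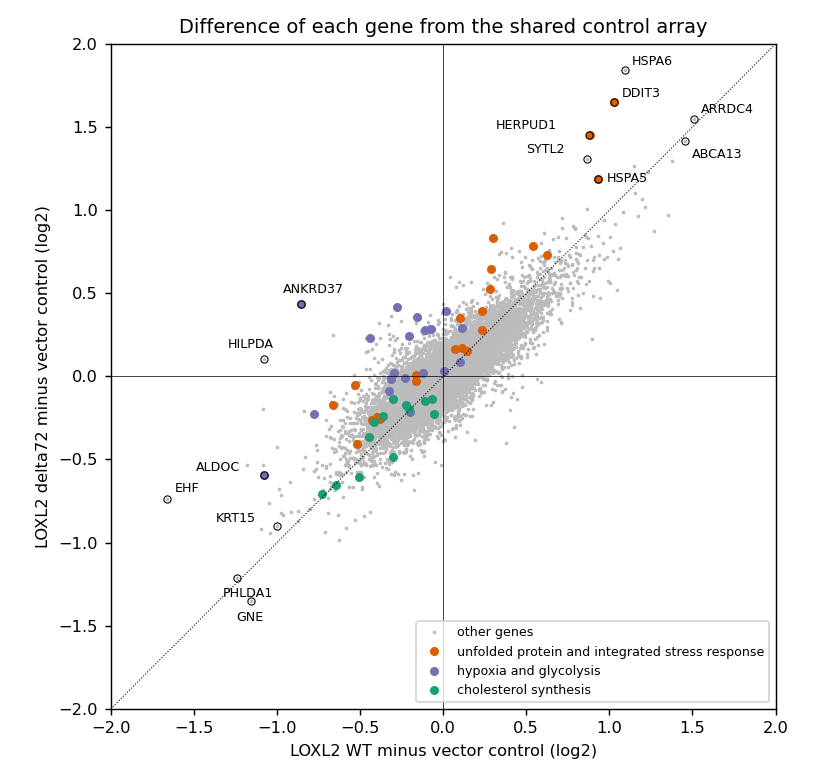
Log2 difference from the vector control of each gene above the filter, for LOXL2 WT (x axis) and LOXL2 delta72 (y axis), with 1 point per gene, members of 3 lists in colour and equality as the dotted line. LOXL2 itself lies outside the axes. Stress response genes such as DDIT3 and HERPUD1 lie above the dotted line, cholesterol synthesis genes lie near it in the lower left, and ANKRD37 lies at -0.86 and 0.43.

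The comparison of both forms with each other does not use the control array. The 2 highest genes were hypoxia-responsive. ANKRD37 was 1.29 higher with delta72 than with WT (2.45-fold, 1 probe set) and HILPDA 1.18 higher (2.27-fold, SD 0.04 over 2 probe sets). ERO1A, an oxidase that drives disulphide formation in the endoplasmic reticulum, was 0.71 higher (SD 0.11 over 2 probe sets), BNIP3, a mitophagy receptor, 0.69 higher (SD 0.24 over 2 probe sets) and NDRG1 0.67 higher. All 22 members of the unfolded protein and integrated stress response list were higher with delta72 than with WT.

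ANKRD37 and HILPDA were the 2 genes at least 2-fold higher with delta72, and 0 genes were at least 2-fold lower. The remaining genes among the 10 highest were EHF at 0.92, TNKS2 at 0.91, CARD17P at 0.89, HSPA6 at 0.75, KLHL34 at 0.70 and IL24 at 0.68. The 10 lowest were RABGAP1L at -0.78, CCDC69 at -0.73, TADA2A at -0.67, ZNRF3 at -0.62, LRRC74A at -0.61, ZNF124 at -0.58, SECISBP2L at -0.58, HHIPL2 at -0.57, GCSH at -0.54 and NAPA at -0.53. CCDC69 (SD 0.55), SECISBP2L (SD 0.42) and RABGAP1L (SD 0.32) differed between their 2 probe sets each.

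The hypoxia and glycolysis list had a median delta72 minus WT difference of 0.36, with 17 of 19 members higher, 3 of them at least 1.5-fold. The median was -0.20 with WT and 0.09 with delta72 against control. NDRG1 was at -0.44 and 0.23 against control, and BNIP3 at -0.28 and 0.41. The stress response list had a median of 0.17, with HERPUD1 at 0.57, DDIT3 at 0.62 and PDIA4 at 0.53. The immediate early list had a median of 0.13, with 15 of 19 members higher, among them IER3 at 0.34 and JUN at 0.26. The NF-kB list had a median of 0.10, with 12 of 15 members higher and CXCL8 at 0.43. TGF-beta and SMAD targets had a median of 0.09, matrix proteases and inhibitors 0.07, with PLAU, the urokinase gene, at 0.41, and p53 targets 0.06. The list medians of 0.13 and below were smaller than the largest difference of a background probe set between both forms, 0.152.

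On the lower side, the DNA replication list had a median of -0.11, with 19 of 24 members lower, the spliceosome list -0.10, with 14 of 19 lower, and the interferon list -0.09, with 13 of 19 lower and RSAD2 at -0.45. The protease (94.7th percentile) and interferon (5.3rd percentile) lists no longer stood apart without the filter, nor did the p53 targets after the lowess correction (97.1st percentile) or the TGF-beta list with the median over probe sets (92.9th percentile).

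**Figure D3:**
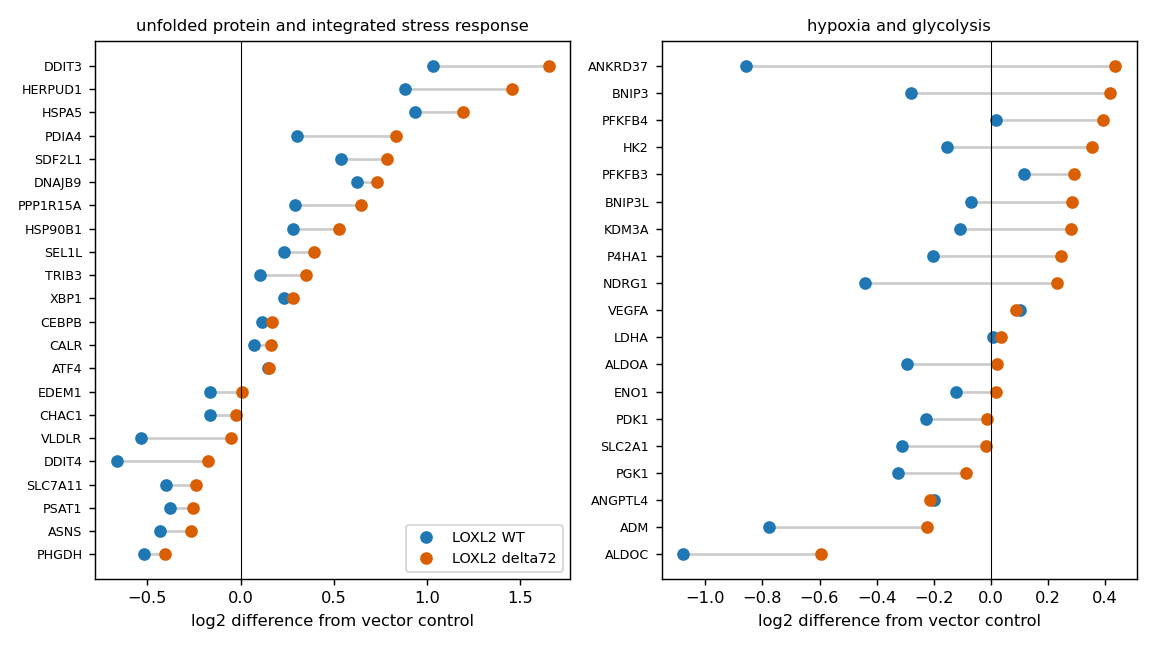
Log2 difference from the vector control (x axis) of each member of 2 gene lists (y axis) with LOXL2 WT and with LOXL2 delta72, with 1 point per array difference and a line between both. All 22 stress response members and 17 of the 19 hypoxia and glycolysis members have their delta72 point to the right of their WT point.

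Lists of epithelial and mesenchymal state lay within the range of random lists as deposited. The epithelial junction list had medians of 0.05 with WT and 0.02 with delta72 against control, with DSC3 at -0.53 and -0.86. CDH1, the E-cadherin gene, was at 0.05 and 0.0045, and was named after its values were seen. The mesenchymal list had medians of -0.11 and -0.000815, with SNAI2 at 0.60 and 0.54 and VIM, the vimentin gene, at -0.22 and 0.17. The extracellular matrix list had medians of -0.11 and 0.07, with TNC, the tenascin C gene, at 0.78 and 0.53. The lysyl oxidase and collagen modification list, without LOXL2, had medians of -0.06 and 0.04, and the squamous differentiation list -0.03 and -0.09. With WT the extracellular matrix list lay below that range under quantile normalization (2.1st percentile), lowess (2.25th) and the median over probe sets (1.1st), and with the last of these it lay above it between both forms (99.05th). Without the filter, the squamous differentiation list lay below the range with delta72 (1.8th percentile) and between both forms (0.05th).

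Other lists within the central 95% of random lists against control were the immediate early genes (-0.09 and -0.03), YAP/TEAD targets (-0.11 and -0.08), TGF-beta and SMAD targets (-0.09 and -0.03), p53 targets (-0.03 and 0.00209), interferon-stimulated genes (0.00166 and -0.08), matrix proteases and inhibitors (-0.12 and -0.08), cytosolic ribosomal proteins (-0.03 and -0.0088) and oxidative phosphorylation (-0.01 and 0.002), with the WT median first. Within that range were also, with WT, the basal squamous (-0.10), heat shock (0.13) and DNA replication (-0.00604) lists and, with delta72, the spliceosome (0.06), NF-kB (-0.08) and hypoxia (0.09) lists. Several of these stood apart under other settings. With the median over probe sets, the YAP/TEAD list lay at -0.175 with WT (0.05th percentile), -0.131 with delta72 (0.45th) and 0.058 between both forms (97.6th), and it was also below the range against control under quantile normalization and lowess. With that median, the basal squamous list lay at -0.246 with WT (0.05th percentile) and the protease list at the 2.0th percentile. The heat shock list lay above the range with WT under quantile normalization (99.25th percentile), the median over probe sets (99.25th) and lowess (98.65th). The NF-kB list lay at the 2.4th percentile with delta72 at the 60th percentile filter. ATF3, an immediate early gene, was at 0.47 and 0.69, JUN at 0.60 and 0.86, and DUSP6 at -0.72 and -0.61. ID1, a SMAD target, was at -0.65 and -0.68, and SKIL at 0.60 and 0.69. MMP14, a membrane-bound matrix protease gene, was at -0.57 and -0.39.

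Between both forms, the medians within the range of random lists were 0.04 for lysyl oxidase and collagen modification, 0.03 for extracellular matrix, 0.05 for the mesenchymal list, -0.02 for epithelial junctions, -0.04 for squamous differentiation, 0.00431 for basal squamous identity, 0.02 for integrins, 0.001 for mitosis, -0.05 for heat shock, 0.00923 for cholesterol synthesis, 0.06 for NRF2 targets, -0.00444 for YAP/TEAD targets, 0.08 for histones, 0.009 for ribosomal proteins, 0.009 for oxidative phosphorylation and 0.03 for the EGFR family. At the 60th percentile filter the lysyl oxidase list (0.185, 100th percentile), the EGFR family (0.13, 99.9th) and the heat shock list (-0.08, 0.85th) stood apart between both forms, and the NRF2 and histone lists did so under quantile normalization and lowess, the histone list also without the filter. Median and mean had opposite signs for the extracellular matrix list with WT (mean 0.02), for the lysyl oxidase list with delta72 (mean -0.05) and for other lists whose median lay within 0.05 of 0.

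**Figure D4:**
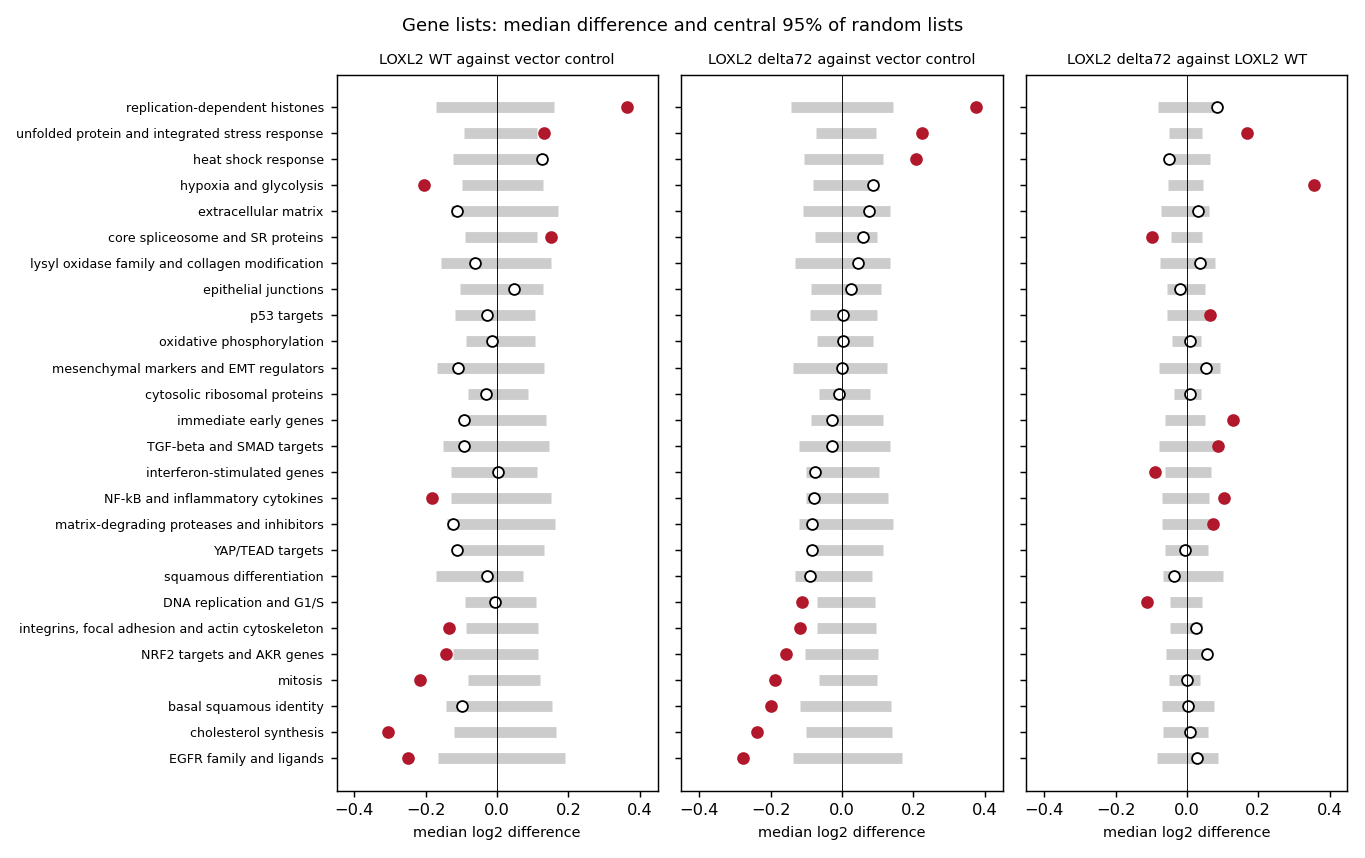
Median log2 difference (x axis) of 26 gene lists (y axis) in each comparison, with grey bars for the central 95% of 10000 random lists and filled points for lists outside it. Cholesterol synthesis lies at -0.30 and -0.24 in the comparisons with control and near 0 between both forms, and hypoxia and glycolysis lies at 0.36 between both forms.

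Markers of other cell types were read because the culture should lack those cells. Of the fibroblast markers 2 of 12 passed the filter, with a median level of log2 6.46 on the control, 6.27 on the WT and 6.23 on the delta72 array and median differences of -0.19, -0.23 and -0.03 in the order WT minus control, delta72 minus control and delta72 minus WT. The 6 endothelial markers above the filter had levels of 5.92, 5.89 and 5.97 and differences of -0.01, -0.04 and -0.05. The 4 leukocyte markers had levels of 6.65, 6.75 and 6.65 and differences of -0.17, -0.17 and 0.01, with CD68 at -0.53 with WT. The 5 markers of simple epithelium had levels of 8.14, 8.06 and 8.24 and differences of -0.16, -0.06 and -0.00319. Among them KRT18 was bright in these cells, at log2 13.64 on the control array, and lower with WT, at -0.28, and with delta72, at -0.32. All 4 lists lay within the central 95% of random lists in each comparison as deposited. Without the filter, 12 markers of simple epithelium were measured, and their medians of -0.247 with WT (0.2nd percentile) and -0.175 with delta72 (0.5th) lay below the range, as did the WT median at the 60th percentile filter (2.1st percentile, 4 markers).

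The control probe sets differed between arrays with the GC content of their probes. Among 16 background probe sets with 10 to 25 G and C bases, the WT minus control difference had a slope of -0.0194 per base and 15 were lower on the WT array. The delta72 slope was -0.0116, with 14 lower. At 25 bases the differences were -0.28 with WT and -0.17 with delta72. For delta72 minus WT the slope was 0.00783, 1 of the 16 was lower with delta72, and the largest difference was 0.152. The GC content of the probes of genes is not given in the sources used here. The hybridisation spike-ins were lower than on the control array too, with medians of -0.156 with WT and -0.232 with delta72 over 9 probe sets, and the labelling spike-ins had medians of -0.148 and -0.0785 over 12. The second probe sets for the same spike-ins had medians of -0.0506 and -0.216 for hybridisation and -0.0742 and -0.0453 for labelling. The log2 excess of the 3' over the 5' probe set of ACTB, a sign of RNA integrity, was 1.26 on the control, 1.46 on the WT and 1.32 on the delta72 array, and that of GAPDH was -0.0058, 0.0029 and 0.002. The GAPDH probe sets read 14.18 and 14.19 on the control array, near the highest value of 14.56, so their difference says little about RNA integrity.

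**Figure D5:**
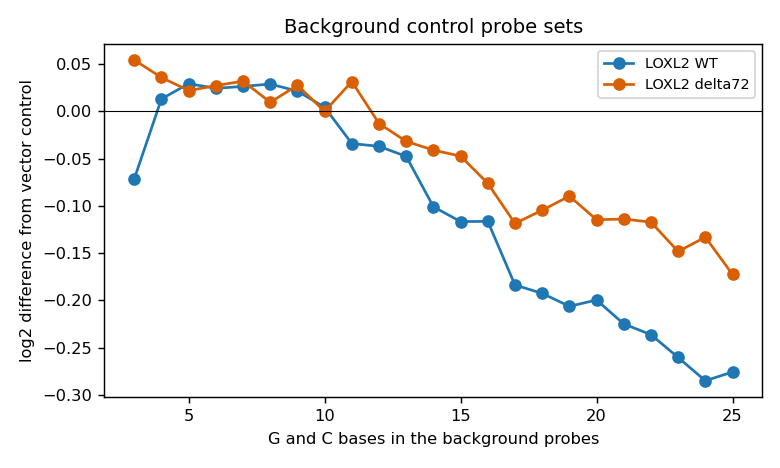
Log2 difference from the vector control (y axis) of the background control probe sets against the number of G and C bases in their probes (x axis), with 1 line per LOXL2 array. At 10 bases the lines lie at 0.00433 with WT and 0 with delta72, and at 25 bases they reach -0.28 with WT and -0.17 with delta72.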

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

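The tests of brightness against probe GC in this part, and the requirement that each difference exceed the probe error, were chosen after the result was seen, whereas the gene lists, the rule for naming genes and the alternatives to the processing other than the lowess correction were chosen before the data were examined. The results here lay on opposite sides of the vector control with LOXL2 WT and with LOXL2 delta72 and, for genes, were at least 1.5-fold apart. The requirement on probe error left out HILPDA, ZNRF3 and the interferon and p53 lists. HILPDA was 0.106 above control with delta72, more than its own probe error (SD 0.0139) but less than the pooled probe error of 0.145. The difference between the forms was not tested, since each form had 1 array.

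Among hypoxia-responsive genes, the hypoxia and glycolysis list was 0.356 higher with delta72 than with WT (-0.203 and 0.0864 against control), and so were ANKRD37 by 1.29 (-0.86 and 0.43), BNIP3 by 0.69 (-0.28 and 0.41), NDRG1 by 0.67 (-0.44 and 0.23) and ERO1A, which is not on the list, by 0.71 (-0.39 and 0.32). A trend of brightness with probe GC as the whole cause is argued against by the 0.356 (SE 0.0324), which exceeds the largest difference between the forms in any background probe set, 0.152. It is not excluded for the WT minus control median alone, since background probe sets differed by up to 0.285 there. The delta72 median of 0.0864 (SE 0.0418) does not decide it, since it was 0.0378 (77.35th percentile) with the median over probe sets. The oxygen or density of a single culture cannot be told apart from an effect of the form of LOXL2, which stays open and untested, because each condition had 1 array.

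Other genes higher with delta72 than with WT were TNKS2 by 0.91 (-0.66 with WT and 0.25 with delta72 against control), KLHL34 by 0.70 (-0.46 and 0.23) and IL24 by 0.68 (-0.31 and 0.37). Genes lower with delta72 than with WT were RABGAP1L at -0.78 (0.38 and -0.40 against control), CCDC69 at -0.73 (0.43 and -0.30) and LRRC74A at -0.61 (0.40 and -0.20). The 2 probe sets of RABGAP1L and the 2 of CCDC69 disagreed on the difference between both forms, as given above. TNKS2, KLHL34, IL24 and LRRC74A rest on 1 probe set each.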

How the results depend on the processing

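The lowess correction was chosen after the control probe sets had been seen. Of 407 differences of named genes, 407 kept their sign under the lowess correction and the shift to a common median, 406 under quantile normalization and 401 with the median over probe sets. The genes were named for large differences, and for part of them the rule required that median to share the sign. Kept signs were thus favoured in advance. With the median over probe sets, 51 of the 407 differences moved by more than the probe error. The filters leave a gene's own difference as it is. The correlation of both forms' differences from control ranged from 0.788 (no filter) to 0.885 (60th percentile filter).

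With the 60th percentile filter, which tests fewer genes, 12 genes were at least 2-fold higher and 7 lower with WT, and 1 was lower with delta72. With the median over a gene's probe sets, 7 were lower with WT and 1 with delta72, and the cause was not tested. The covariance was 0.0422 both with the median over probe sets and with no filter, and the cause was not tested. At 1.5-fold, 226 genes were higher and 106 lower with WT, 157 higher and 61 lower with delta72, and 22 higher and 5 lower with delta72 than with WT. At 3-fold the counts were 1 and 1 for WT, 3 and 0 for delta72, and 0 higher between the forms. The counts of genes higher than control include LOXL2, which is the 1 gene at least 3-fold higher with WT. The thresholds themselves make these counts differ.

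Of 30 calls of a list outside the central 95% of random lists, 30 were kept under quantile normalization, 29 under the lowess correction and the 60th percentile filter, and 26 with the median over probe sets and with no filter. The shift to a common median moves a list and its random lists alike and tests no call. Quantile normalization and the lowess correction each added 6 calls, the median over probe sets 8, the 60th percentile filter 5 and no filter 4. Among these was the hypoxia list above control with delta72, at the 98.9th percentile with no filter and the 99.8th with the 60th percentile filter, whereas it lay at the 77.35th with the median over probe sets. These counts cover the gene lists and leave out the markers. No list called as deposited changed sign. The signs of list medians were kept in 79 of 87 cases under quantile normalization, 78 of 87 under lowess, 76 of 87 with the median over probe sets, 83 of 90 with no filter and 73 of 81 with the 60th percentile filter, and the medians that changed sign were of lists inside the random range. In size, 18 of 87 list medians moved by more than the probe error with the median over probe sets. With no filter 13 of 90 did so, and with the 60th percentile filter 19 of 81.

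The pseudocounts planned for linear values were not run, because the deposited values were already log2. Marker lists with fewer than 3 members above the filter gave no value. Leaving out a replicate was not possible with 1 array per condition. No paired analysis was possible because each condition had 1 array. Background depends on probe GC, and background probe sets read up to 10.84 on the control array, so passing a filter does not place a probe set above background.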

Other observations

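The tests of endoplasmic reticulum load and of brightness against probe GC, the zinc finger group and the genes beyond the naming rule in this part were chosen after the result was seen.

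Other endoplasmic reticulum genes, beyond the lists, were read beside HSPA5 and HERPUD1. DNAJB11 was at 0.79 with WT and 0.89 with delta72, DNAJC3 at 0.72 and 0.89, HYOU1 at 0.59 and 0.80, MANF at 0.46 and 0.76, CRELD2 at 0.51 and 0.57, and PDIA6 at -0.02 and 0.19, and all 6 were higher with delta72 than with WT. TXNIP, a relative of ARRDC4 that was dim here (log2 5.82 on the control array), was at -0.25 and -0.24, whereas ARRDC4 was 2.85-fold and 2.93-fold higher.

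Of the 22 stress response genes, 14 were higher with WT than control, and all 14 were higher still with delta72, while 8 were lower with WT. For the 14, a trend of brightness with probe GC as the whole cause is argued against. The background probe sets differed less from control on delta72 than on WT, whereas the delta72 minus WT median over these 14 was 0.244. The median over all 22 members, 0.169 (SE 0.0301), does not decide it, since background probe sets were up to 0.152 higher with delta72 than with WT. On delta72, 7 of the 8 members lower with WT lay between control and WT, as in such a trend. A candidate explanation is a load of the endoplasmic reticulum by the expressed protein, because LOXL2 is secreted through it. The 9 members that act there had a delta72 minus control median of 0.732 and the 6 of the amino acid response -0.248. The gap was 0.980 (SE 0.0959), but the members were parted after their values were seen. Their delta72 minus WT medians of 0.244 and 0.147 differed by only 0.0961 (SE 0.0744). Both SEs hold probe error alone and leave out the spread between the genes of a group. Whether the higher values with delta72 than with WT were specific to the members that act there is thus not settled. Load of the endoplasmic reticulum cannot be told apart from an effect of the single culture, since each condition had 1 array.

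The 291 genes named ZNF with a number had a median of 0.146 with WT and 0.103 with delta72, with 67.4% and 66.3% higher, and made up 10.2% of the genes at least 1.5-fold higher with WT against 2.38% of all genes. A trend of brightness with signal level as the whole cause is argued against, since random lists of the same brightness had WT medians from -0.0532 to 0.00505 in their central 95%, while the lowess correction, which moved little, left the zinc finger median at 0.142 (SE 0.0125). A trend with probe GC may contribute, as the ratio of the delta72 to the WT median, 0.703 (SE 0.0946), lay within 2 SE of the ratio of the background slopes, 0.596. That ratio does not single out probe GC, because the median ratio over the 331 genes at least 1.5-fold different with WT was 0.783, and the GC content of their probes is not known here. An effect of LOXL2 on these genes stays open and untested.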
